A study of Homo sapiens with 4 samples.

How the data were processed

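Open chromatin was profiled by ATAC-seq, in which a transposase inserts sequencing adapters into accessible DNA, in 4 established human cancer cell lines. SKBR3 and T47D are labelled as breast cancer and HCT116 and RKO as colorectal cancer. Each line is represented by 1 library of single-end reads of 60 bp, per the labels. SKBR3 and HCT116 were grown in the same medium, McCoy's 5A, T47D in RPMI and RKO in DMEM, per the labels' protocols. Tagmentation and library preparation used a commercial ATAC-seq kit, per the labels' protocols.

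The authors deposited 1 peak list per library. Reads were processed with Bowtie2 2.4.1 and MACS3 3.0.0b3 on the hg19 build, per the submitters' processing notes. Sequence names of the hs37d5 version of that build, including its decoy sequence and unplaced contigs, were present in every list. Per the file headers, peaks were called on each library separately with a q cutoff of 0.1, without a control library, in single-end mode, with a fragment model built from the data, an effective genome size of 2910000000 bp and 1 tag kept per position. No shift of reads to the transposase cut site is named in the command lines in the headers, so each tag was extended by the modelled fragment length of 105 to 117 bp, and summits mark the centre of extended tags and not insertion sites. Whether reads were filtered on mapping quality before peak calling is not given in the sources used here. The header of the T47D list names its input T45D; the list was assigned to T47D by the sample it was deposited under.

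Each deposited row holds a position, the pileup signal at the summit (tags stacked after duplicate removal, not scaled between libraries), a fold enrichment (the authors' ratio of the pileup to the local background), and −log10 p-values and −log10 q-values from the authors' MACS3 run. These are values of each peak within its own library, so they were used only to describe, rank or filter peaks within a list. The lists were compared by the presence or absence of an overlapping call. Coordinates are 1-based hg19 positions as the files give them.

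Rows outside chromosomes 1 to 22 and X were left out of the comparisons; they made up 0.975% to 1.68% of the lists. No list repeated an interval, and none skipped a peak number. The 4 lists were merged into a union of regions (overlap of at least 1 bp), and each region was scored as called or not called in each line. Pairwise overlap was compared with 20 shuffles of the peaks to uniform positions within their chromosomes, which include assembly gaps. Shares are given with exact Clopper-Pearson 95% intervals. Intervals cover counting error only, since PCR copies, cultures and libraries add spread that 1 library per line cannot show. No p-value between lines is given: each line has 1 library, and 2 breast lines against 2 colorectal lines allow only 3 ways to pair the lines, so no share of pairings can go below 0.333.

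The local background that MACS used at each peak was recovered from the deposited pileup and fold values, since the fold is (pileup + 1) / (background + 1). Its lowest value in each list lay close to tags × fragment length / genome size from the header (0.173 by both routes in SKBR3, 0.206 in T47D and 0.118 in RKO, and 0.0388 against 0.0389 in HCT116), and backgrounds are given as multiples of that genome-wide level. Peaks at that level were left out: 32.7% of the peaks in SKBR3, 30.0% in RKO, 19.4% in T47D and 2.37% in HCT116. The median multiple over all peaks was 1.76 in SKBR3, 1.88 in RKO, 2.41 in T47D and 4.13 in HCT116. Multiples of different lines are therefore not on one scale. To account for called signal inside the 10 kb background window, log2 background was regressed within each list on called signal nearby. Called signal was the log2 sum of pileup × peak length within 5 kb of the summit. Across peaks it correlated with log2 background at r = 0.918 (SKBR3) to 0.935 (RKO), so unadjusted multiples largely follow called signal. Median residuals were taken per 1 Mb bin with at least 10 peaks in every line (1275 bins), centred within each line, and compared with the median of the other 3 lines. Unadjusted log2 backgrounds were centred and compared in the same way, so these differences are not the ratios of the multiples given for each line. The code was tested on simulated data: 0 of 17384 simulated regions were given a wrong pattern of lines, and a simulated bin with a 4-fold raised background ranked 1 of 200 bins. Simulated regions were too far apart to run together, and the bin was ranked within a single list. Crowded peaks and differences between lines were therefore not tested.

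The comparisons of peak counts, of patterns of lines and of tissues, their alternatives, and the rule for named regions were set before the data were examined. The rule names the 3 regions per tissue direction with the highest value of the lower of the pair's percentile ranks of fold enrichment within their own lists. Its condition on distance to a transcription start site, and the planned analyses of the PVRL4 locus, of gene promoters, of sequence motifs and of genomic position, needed an hg19 annotation or sequence. The gene table used here is on GRCh38, no coordinates were converted, and so no peak was assigned to a gene and these 4 analyses are not reported here. The windows of 100 kb, the 500 kb bins, the shares by chromosome, the local background and the stretches without peaks were chosen after the data were seen. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1; figures were drawn with matplotlib 3.10.9.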

Results

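Open chromatin was mapped in SKBR3 and T47D, 2 breast cancer lines, and in HCT116 and RKO, 2 colorectal cancer lines, in a series concerned with the transcriptional control of PVRL4 by FOS family proteins. There was 1 ATAC-seq library per line. After removal of duplicate positions the libraries held 4313512 tags in SKBR3, 5450100 in T47D, 1057628 in HCT116 and 3262240 in RKO. Duplicates made up 47% of the tags in SKBR3, 49% in T47D and 63% in both colorectal lines. HCT116 was the shallowest library, so the absence of a call there weighs less than in the other lines.

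The first comparison asked how much chromatin was called open in each line. SKBR3 had the most called peaks, with 111635 on chromosomes 1 to 22 and X, covering 27.6 Mb. T47D had 77458 peaks covering 21.2 Mb, RKO 66594 covering 15.3 Mb and HCT116 39899 covering 8.04 Mb. The median peak was 199 bp wide in SKBR3, 211 bp in T47D and 168 bp in both HCT116 and RKO. The order of the breast lines depended on the threshold. At a −log10 q of at least 10, T47D had 37325 peaks and SKBR3 33536, against 20592 in RKO and 10000 in HCT116. Such strong calls made up 48.2% of the T47D list, but 30.0% of the SKBR3 list, 30.9% of the RKO list and 25.1% of the HCT116 list. The number of peaks did not follow depth alone, since T47D had more tags than SKBR3 and fewer peaks. Per 1000 tags, 25.9 peaks were called in SKBR3, 14.2 in T47D, 20.4 in RKO and 37.7 in HCT116.

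**Figure D1:**
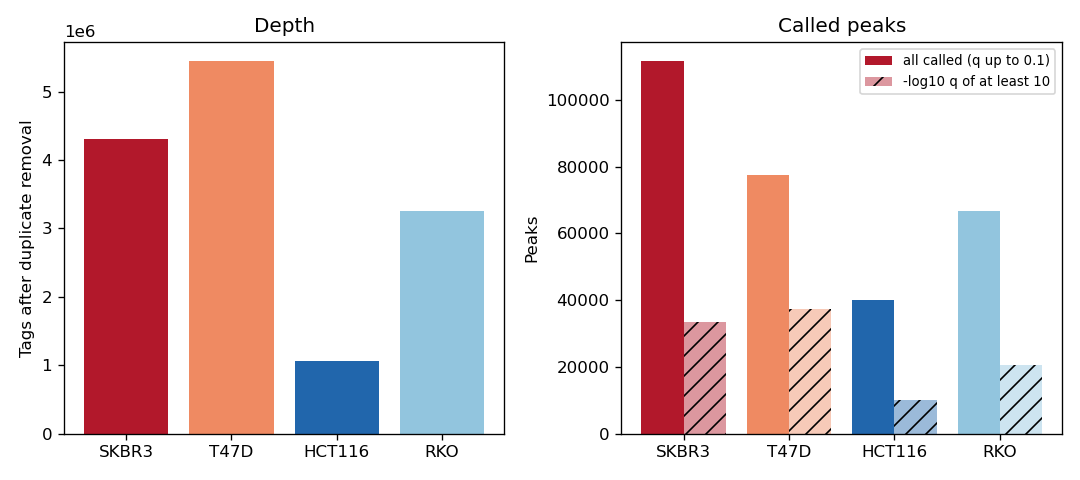
Number of tags kept after duplicate removal (left) and number of called peaks (right) in the 1 library of each line; solid bars are all peaks at the authors' cutoff and hatched bars those with a −log10 q of at least 10. T47D had the most tags (5450100) and SKBR3 the most peaks (111635), and HCT116 had the fewest of both.

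The second comparison asked which open regions the lines had in common. The 4 lists merged into 167619 regions. Of these, 19761 regions (11.8%, 95% interval 11.6 to 11.9) were called in all 4 lines, 13778 in 3 lines, 33547 in 2 lines and 100533 (60.0%) in 1 line. Regions termed open are called regions, and a region not called in a line need not be closed there. Of the peaks called in 1 line only, 5.05% (HCT116) to 16.9% (T47D) had a −log10 q of at least 10. Regions called in all 4 lines had a median merged width of 469 bp. A merged region spans the peaks of every line called in it, so this width is not on one scale with that of single-line regions. SKBR3 alone contributed 51143 regions, RKO alone 24754, T47D alone 19309 and HCT116 alone 5327. With every list shortened to the length of the HCT116 list, the regions of a single line numbered 12695 in SKBR3, 12408 in RKO, 10325 in HCT116 and 8721 in T47D. At a −log10 q of at least 10 the order changed, to 12987 in T47D, 11502 in SKBR3, 4863 in RKO and 796 in HCT116.

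Shared peaks were the strong and wide ones within every list, though wide peaks also meet an overlap of 1 bp more easily. In SKBR3, peaks also called in the other 3 lines had a median fold enrichment of 9.46 (interquartile range 6.48 to 13.0) and a median width of 322 bp. SKBR3 peaks called in no other line had a median fold of 4.26 (3.41 to 5.90) and a width of 153 bp. The same order held in T47D, with medians of 12.5 and 5.05, in RKO, with 9.34 and 4.16, and in HCT116, with 7.02 and 4.05. Of the SKBR3 peaks, 45.8% (45.5 to 46.1) were called in no other line, against 37.2% (36.8 to 37.5) in RKO, 24.9% (24.6 to 25.2) in T47D and 13.4% (13.0 to 13.7) in HCT116. Among the strongest 10% of each list by q, 92.1% of SKBR3 peaks, 97.0% of RKO peaks and 98.7% of both T47D and HCT116 peaks were called in at least 1 other line. In the weakest 10% these shares were 23.6%, 31.4%, 46.2% and 70.9%.

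**Figure D2:**
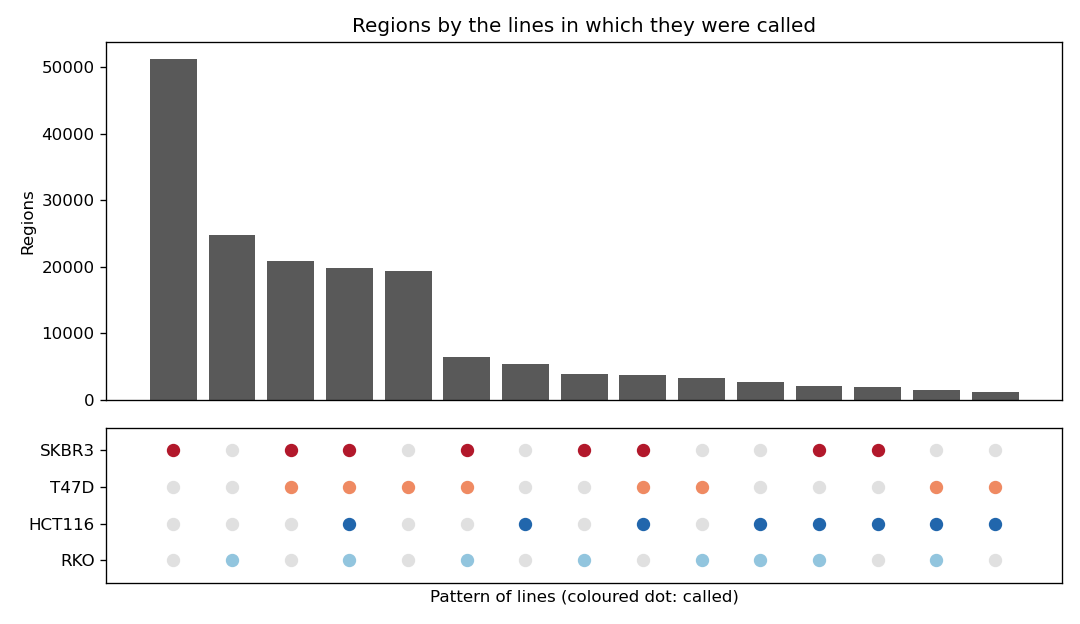
Number of merged regions for each of the 15 patterns of lines; coloured dots below a bar mark the lines in which those regions were called. Regions of SKBR3 alone (51143) form the tallest bar, and regions of both breast lines (20855) and of all 4 lines (19761) are the most frequent shared patterns.

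The third comparison set the breast lines against the colorectal lines. Lines of the same tissue shared a larger part of their called regions than lines of different tissues. Library traits split the lines in the same way. Duplicates were 63% in both colorectal lines, against 47% in SKBR3 and 49% in T47D. Modelled fragments were 107 bp in HCT116 and 105 bp in RKO, against 117 bp in SKBR3 and 110 bp in T47D. Such traits cannot be told apart from tissue here. SKBR3 and T47D had 50794 regions in common, 37.7% (37.4 to 37.9) of the regions open in either. HCT116 and RKO had 26060 in common, 34.1% (33.8 to 34.5). The 4 pairs of different tissue shared 22.7% (SKBR3 and RKO), 22.8% (SKBR3 and HCT116), 28.3% (T47D and RKO) and 29.7% (T47D and HCT116). With lists of equal length the breast pair shared 42.5% (42.1 to 42.9) and the colorectal pair 40.7% (40.3 to 41.1), against 27.2% to 37.3% in the other pairs.

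Regions open in both lines of one tissue and in neither line of the other numbered 20855 for breast and 2699 for colorectal, 23554 in all. Pairing the lines the other ways gave 5041 regions (SKBR3 with HCT116 and T47D with RKO) and 4952 regions (SKBR3 with RKO and T47D with HCT116). The first of these pairings also joins the lines grown in the same medium: SKBR3 and HCT116 alone shared 1829 regions. In the full lists the colorectal pair did not stand out by itself. Its 2699 regions were fewer than the 3845 of SKBR3 and RKO alone and the 3212 of T47D and RKO alone. At a −log10 q of at least 10 it had 410, against 630 and 2487. With equal list lengths it had 4186, more than any pair of different tissue (778 to 1943). With equal list lengths the tissue total was 10750, against 3136 and 2721. The excess of breast over colorectal regions was 7.73-fold in the full lists and 1.57-fold, 6564 against 4186, with lists of equal length. It was 21.6-fold, 8844 against 410, at a −log10 q of at least 10, and 28.9-fold, 5107 against 177, where that threshold was required in both lines with no call elsewhere. Reaching a fixed −log10 q depends on depth, and HCT116 had 1057628 tags against 5450100 in T47D. The larger excesses at that threshold therefore do not show a larger difference between the tissues. No test between the tissues is given: relabelling the lines gives only 3 pairings, and the smallest share these allow is 0.333.

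**Figure D3:**
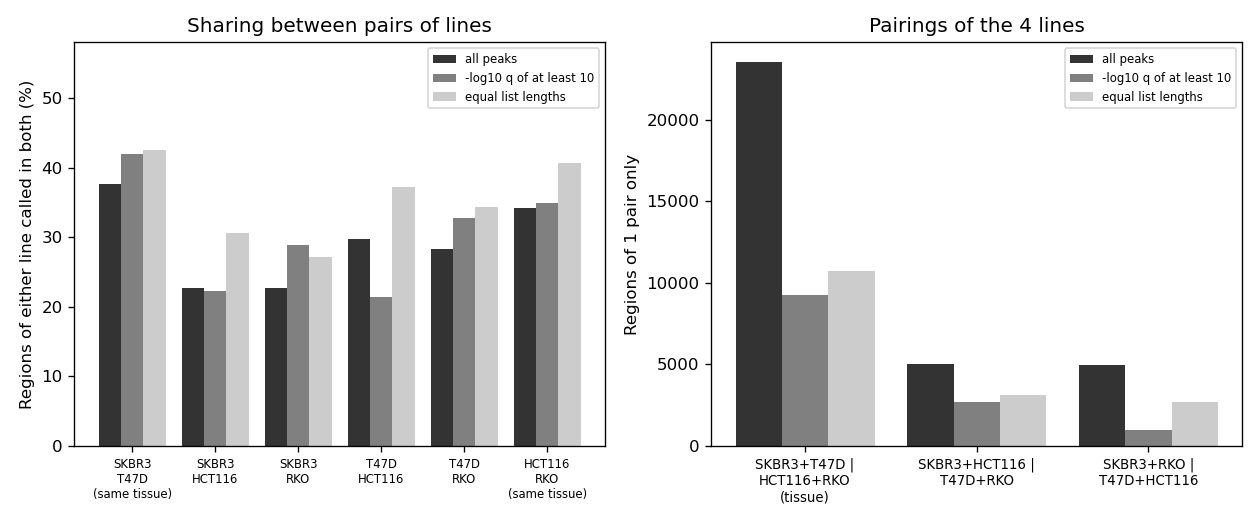
Left, regions called in both lines as a percentage of the regions called in either, for each pair of lines; right, number of regions called in both lines of 1 pair and in neither of the other, for the 3 ways to pair the lines; shades mark all peaks, peaks with a −log10 q of at least 10, and lists of equal length. The tissue pairing (23554 regions with all peaks) stands above the other pairings in each of these settings.

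The share of one list overlapped by another also depends on the length of the other list. In the full lists the line of the same tissue overlapped most peaks for the breast lists and fewest for the colorectal lists. Of the 111635 SKBR3 peaks, 52469 were overlapped by T47D (95% interval 46.7% to 47.3%). They were overlapped by RKO at 29.8% (29.5 to 30.1) and by HCT116 at 24.8% (24.6 to 25.1). T47D peaks were overlapped by SKBR3 at 67.0% (66.7 to 67.4), by RKO at 40.9% (40.5 to 41.2) and by HCT116 at 33.9% (33.5 to 34.2). HCT116 peaks were overlapped by SKBR3 at 72.0% (71.6 to 72.5), by T47D at 69.2% (68.8 to 69.7) and by RKO at 68.7% (68.2 to 69.1). RKO peaks were overlapped by SKBR3 at 50.4% (50.1 to 50.8), by T47D at 49.2% (48.9 to 49.6) and by HCT116 at 39.8% (39.4 to 40.2). Shuffled peaks were overlapped at 0.643% to 2.10%. As a multiple of the shuffled share, the order was another. The line of the same tissue was then highest for the colorectal lists, at 63.0 for HCT116 by RKO and 61.9 for RKO by HCT116. For the breast lists HCT116 was highest, at 38.2 for SKBR3 and 47.8 for T47D, against 32.5 and 32.0 by the other breast line. With lists of equal length the line of the same tissue overlapped most peaks in all 4 lists. T47D peaks were overlapped at 59.8% by SKBR3, 53.0% by HCT116 and 50.6% by RKO, and SKBR3 peaks at 59.9% by T47D, 46.0% by HCT116 and 42.4% by RKO. HCT116 peaks were then overlapped at 59.1% by RKO, 56.6% by T47D and 48.7% by SKBR3, and RKO peaks at 56.7% by HCT116, 52.9% by T47D and 43.7% by SKBR3.

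The strongest regions of the breast pair lay on chromosomes 1, 5 and 2. The region at chromosome 1, 145281325 to 145281726 (hg19) had a fold enrichment of 24.7 in SKBR3 and 25.7 in T47D, and the lower of its percentile ranks within the 2 lists was 99.9. At chromosome 5, 179740697 to 179741048, the folds were 21.8 and 25.7. At chromosome 2, 30144490 to 30144725, they were 21.6 and 26.3. The strongest regions of the colorectal pair lay on chromosome 3, 197798830 to 197799080, with folds of 21.1 in HCT116 and 27.9 in RKO, on chromosome 1, 155931778 to 155932181, with folds of 15.6 and 18.1, and on chromosome 12, 109232151 to 109232522, with folds of 15.3 and 20.1. None of these 6 regions was called in a line of the other tissue at the authors' cutoff. The genes at these positions were not looked up, as no hg19 annotation was used here.

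The windows of 100 kb with the most tissue-shared regions were picked for their counts, and no expected maximum over windows was computed, so they describe positions and do not test for clustering. For breast the highest count was on chromosome 11, 72900001 to 73000000, with 13 such regions among 28, and 7 with lists of equal length. A window on chromosome 5, 167700001 to 167800000, held 10 among 24, and 8 with lists of equal length. Other windows with 10 such regions were chromosome 1, 94000001 to 94100000, chromosome 10, 134200001 to 134300000, chromosome 11, 126200001 to 126300000, and chromosome 20, 60900001 to 61000000; with lists of equal length they held 2, 4, 6 and 5. For colorectal the highest count was 4: chromosome 8, 82100001 to 82200000 and 95200001 to 95300000, and chromosome 9, 21600001 to 21700000. With lists of equal length these held 3, 4 and 4. Chromosome 10, 112100001 to 112200000, with 3 in the full lists, then held 5. In the window on chromosome 9 SKBR3 and T47D had no called region, HCT116 had 5 and RKO 11. The window at chromosome 12, 65800001 to 65900000, held 3 regions, all of them called in HCT116 and RKO and in neither breast line. As a share of each chromosome's regions, breast-shared regions ranged from 9.86% (9.12 to 10.6) on chromosome 19 to 15.2% (13.7 to 16.8) on chromosome 21.

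In the full lists the share of peaks on a chromosome differed most between lines on chromosome 19. It was 3.65% (3.54 to 3.76) in SKBR3, 4.57% (4.42 to 4.72) in T47D, 4.97% (4.81 to 5.14) in RKO and 5.27% (5.05 to 5.49) in HCT116. With lists of equal length SKBR3 was still lowest there, at 4.88%, and RKO was highest, at 5.96%. Other chromosomes then differed more, with 4.91% (T47D) to 6.48% (SKBR3) on chromosome 7 and 5.68% (T47D) to 7.21% (HCT116) on chromosome 2. Chromosome 20 held 3.53% (3.42 to 3.64) of SKBR3 peaks, 3.09% (2.97 to 3.21) of T47D peaks, 2.86% (2.70 to 3.03) of HCT116 peaks and 2.67% (2.54 to 2.79) of RKO peaks. Chromosome 7 held 6.27% (6.12 to 6.41) of SKBR3 peaks and 4.93% to 5.48% of those of the other lines. Chromosome 9 held 4.85% (4.69 to 5.02) of RKO peaks and 3.80% to 4.34% elsewhere. SKBR3 stayed highest on chromosomes 20 and 7 and RKO on chromosome 9 with lists of equal length.

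The local background under the peaks differed between lines at some positions. In SKBR3 the background at chromosome 17, 37 to 38 Mb, was 16.5 times the genome-wide level (median of 121 peaks), against 6.68 times in T47D, 6.33 in HCT116 and 6.52 in RKO. With each line centred on its own median over the bins, the log2 excess over the median of the other lines was 1.81 before and 0.70 after adjustment for called signal nearby. After adjustment the next bins lay above the other lines in both breast lines and below them in both colorectal lines. At 38 to 39 Mb the differences were 0.47 in SKBR3, 0.43 in T47D, -0.44 in HCT116 and -0.43 in RKO. At 39 to 40 Mb they were 0.37, 0.39, -0.37 and -0.43. These differences do not separate a raised breast background from a lowered colorectal one. On chromosome 8, 124 to 125 Mb, the background was 9.93 times the genome-wide level in SKBR3 and 2.68 to 3.86 times in the other lines. The excess on the centred log2 scale was 1.87 before and 0.57 after adjustment. After adjustment, 8 bins of 1 Mb in SKBR3 lay more than 3 SD above the other lines (SD 0.18 on the log2 scale over 1275 bins). Of these, 7 were on chromosome 8, between 71 and 125 Mb, and 1 was the bin on chromosome 17. Chromosome 8 held 4.71% of the bins compared. It was not raised as a whole in SKBR3, with 27 of 60 bins above the other lines and a median of -0.031, and bins in the same span lay below them, such as 82 to 83 Mb at -0.35 and 104 to 105 Mb at -0.51. On chromosome 20, 32 of 37 bins lay above the other lines in SKBR3, with a median of 0.18, as did 23 of 37 bins in T47D, with a median of 0.093, 12 of 37 in HCT116 and 7 of 37 in RKO. RKO had 9 bins over 3 SD, led by chromosome 7, 130 to 131 Mb, at 19.1 times its genome-wide level against 3.41 to 7.99 times in the other lines. T47D and HCT116 had 3 such bins each.

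**Figure D4:**
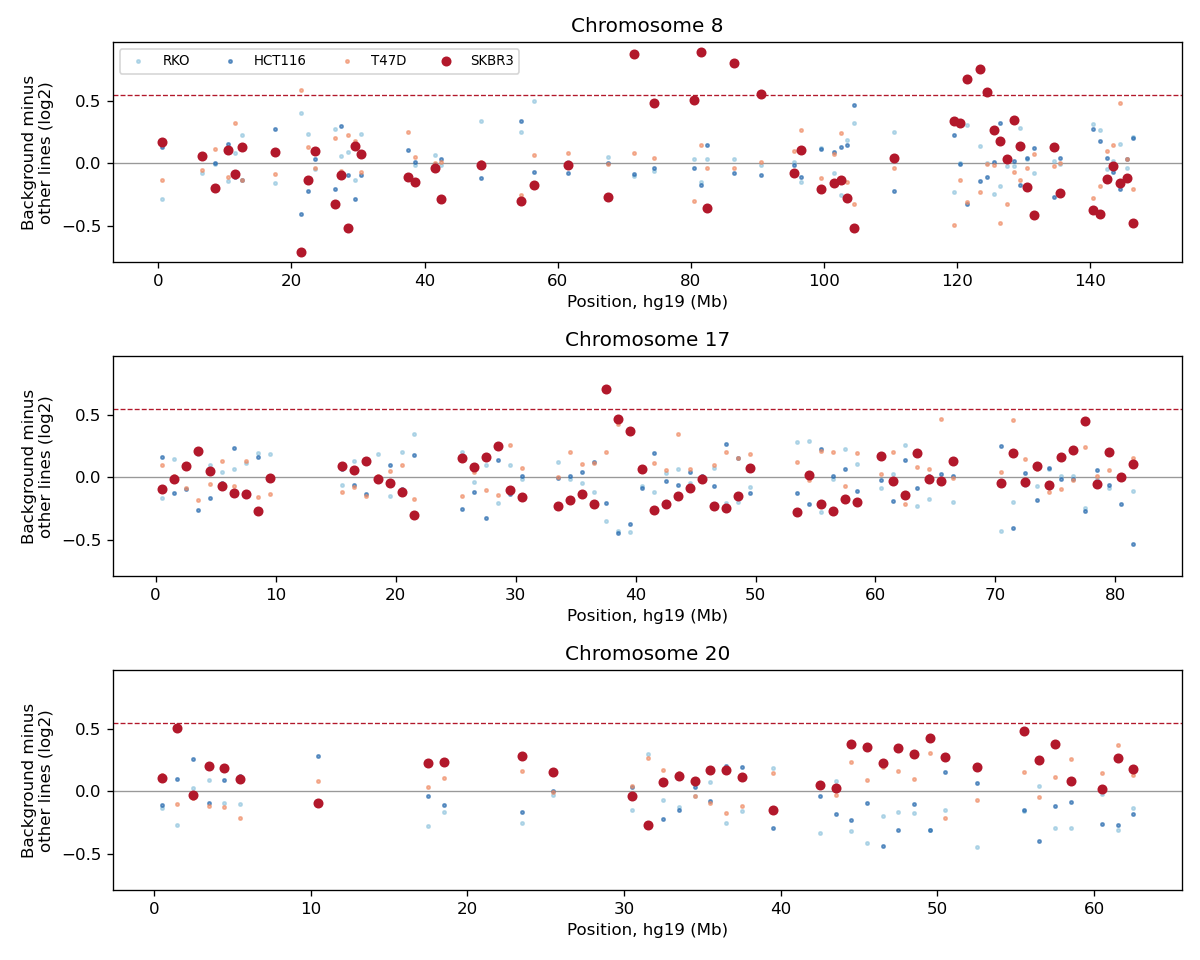
Local background per 1 Mb bin in each line minus the median of the other 3 lines, on the log2 scale after adjustment for called signal, along chromosomes 8, 17 and 20 (hg19, Mb); large points are SKBR3 and the dashed line marks 3 SD. SKBR3 bins pass the line on chromosome 8 (7 bins) and at 37 to 38 Mb on chromosome 17, and most SKBR3 bins of chromosome 20 lie above 0.

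Some stretches without a peak in one line crossed many regions open in the other 3. HCT116 had no peak for 5.76 Mb of chromosome 8, between 111946995 and 117706039, where SKBR3 had 290 peaks, T47D 99 and RKO 87, and where 11 regions were open in all of those 3 lines. It had none for 378 kb of chromosome 14, between 106714368 and 107092660, across another 11 such regions, nor for 2.77 Mb of chromosome 16, between 78156812 and 80930069, across 9. With HCT116 calls permuted among regions open in the same number of other lines, the longest run crossed at most 10 such regions in 1000 permutations, and 3 of them reached the 9 regions of the stretch on chromosome 16. The permutations break up any tendency of neighbouring regions to be called together, so they speak only against calls scattered singly. Nor do they match regions on peak strength, so weak regions missed together at the depth of the HCT116 library are not excluded. Having no peak does not exclude a few missed calls. As the stretches were picked for having no peak, no counting limit is given for them.

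In SKBR3 the stretch that crossed most such regions was on chromosome X, between 114885500 and 115057307. T47D had 34 peaks there, RKO 24 and HCT116 13, and 13 regions were open in all 3. The largest number in 1000 permutations was 5. These permutations scatter calls singly, so they do not allow for a row of closely spaced regions missed together. The 13 regions are therefore not 13 separate absences, and the sequence of the stretch was not looked up. Neighbouring summits were a median of 3005 bp apart in HCT116 (interquartile range 2974 to 3017), with 9 of 12 spacings between 2800 and 3200 bp, and 2981 bp in RKO (2208 to 3018), with 13 of 23 in that range. In T47D they were a median of 2313 bp apart (646 to 2358), with 0 of 33 in that range. Over chromosome X as a whole the medians were 47895 bp in HCT116, 29342 bp in RKO and 23440 bp in T47D. In T47D every second summit was a median of 2989 bp apart, and 27 of these 32 distances lay between 2800 and 3200 bp. SKBR3 also had no peak for 945 kb of chromosome 8, between 104656469 and 105601209, across 5 such regions. On chromosome 19 it had none for 1.17 Mb, between 22681584 and 23850832, across 4. Of 1000 permutations, 1 and 11 reached these numbers. The longest such stretches in T47D and RKO crossed 4 regions each, as 73 and 622 of 1000 permutations did or exceeded.

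**Figure D5:**
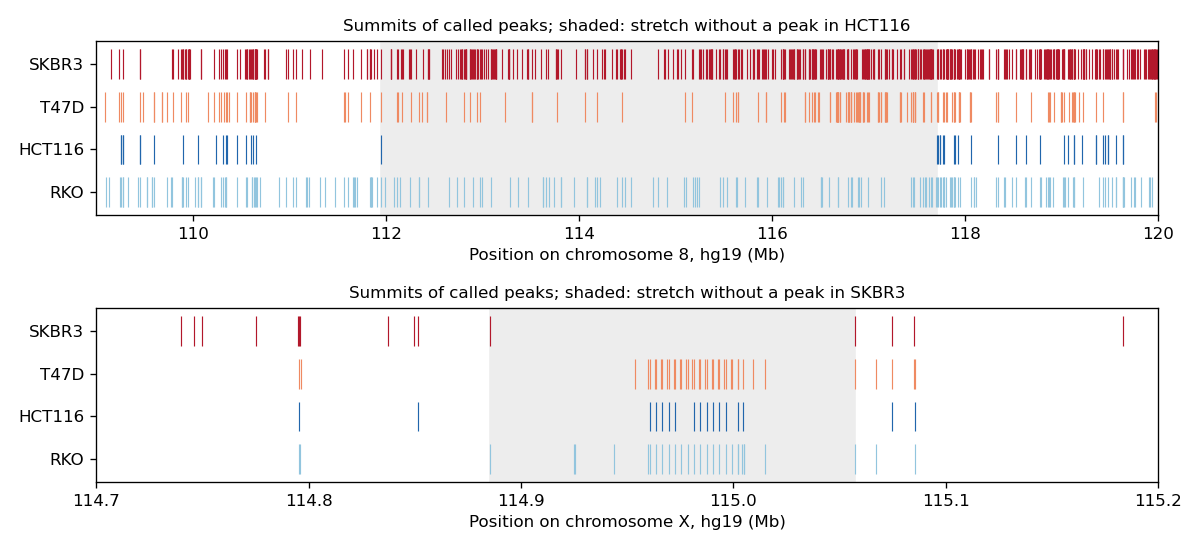
Summits of called peaks (ticks) in each line along chromosome 8 (top) and chromosome X (bottom), in hg19 Mb; shading marks the stretch without a peak in HCT116 (top, 5.76 Mb) and in SKBR3 (bottom). On chromosome X the other 3 lines have a dense row of peaks (34 in T47D, 24 in RKO and 13 in HCT116) that SKBR3 lacks.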

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

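Peaks were also called on sequences outside the chromosomes compared, which no comparison above uses. The decoy sequence of the reference held 902 peaks in SKBR3, 925 in T47D, 270 in HCT116 and 889 in RKO. Unplaced contigs held 241 peaks in SKBR3, 259 in T47D, 100 in HCT116 and 224 in RKO. The mitochondrial sequence held 5 peaks in SKBR3, 4 in T47D, 4 in RKO and 3 in HCT116. Apart from the last, these counts exceed 3, a fixed limit used to list them. That limit does not measure how many peaks absent signal would give, and no control library was used here to set the counts against.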

How the results depend on the processing

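The added threshold (q of 0.05) and the run without HCT116 were chosen after seeing the data; every other setting was planned. The cause of the moves below was not tested beyond what each setting removes. X left out, no count moved over 1.5 times; without HCT116, 24572 regions were open in both breast lines and not in RKO. The tissue total stayed above both other pairings in each of the 7 settings that gave all pairing totals, the reported one included. At a −log10 q of at least 10, peaks fell to 33536 (SKBR3), 37325 (T47D), 10000 (HCT116) and 20592 (RKO), the union to 55699, regions of all 4 lines to 6704, and regions of 1 line to 11502 (SKBR3), 12987 (T47D), 796 (HCT116) and 4863 (RKO), which put T47D above SKBR3. The pairing totals became 9254, 2694 and 964, with 8844 breast and 410 colorectal regions. Requiring that threshold in both lines and no call elsewhere gave 5107 breast and 177 colorectal regions and totals of 5284, 205 and 156. Equal list lengths gave a union of 82485, single-line regions of 12695 (SKBR3), 8721 (T47D), 10325 (HCT116) and 12408 (RKO), 6564 breast and 4186 colorectal regions, and totals of 10750, 3136 and 2721.

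Overlapped shares are given for T47D by SKBR3, HCT116 by SKBR3, RKO by SKBR3, HCT116 by T47D, RKO by T47D and HCT116 by RKO, in this order. They were 56.2%, 79.5%, 59.3%, 83.7%, 70.2% and 78.8% at a −log10 q of at least 10, and 59.8%, 48.7%, 43.7%, 56.6%, 52.9% and 59.1% with equal list lengths. They were 64.6%, 68.0%, 47.7%, 64.5%, 45.7% and 65.2% with summits extended by 100 bp, and 65.5%, 69.8%, 48.4%, 67.8%, 47.9% and 66.6% with an overlap of at least 50% of the shorter peak. At a q of 0.05, 4 shares moved beyond their interval, to 66.2% (T47D by SKBR3), 51.8% (RKO by SKBR3), 51.5% (RKO by T47D) and 68.1% (HCT116 by RKO). No replicate could be left out and no paired analysis was possible because each line has 1 library. Alternatives for the PVRL4 locus, gene lists, motifs and genomic position were not run. Depth limits what an absent call shows, most of all in HCT116 with 1057628 tags.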

Other observations

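Single lines had local concentrations of peaks, in bins picked after their counts were seen. In the 500 kb from 70500001 on chromosome 7 (hg19), SKBR3 had 27 peaks, T47D 1, and HCT116 and RKO none. SKBR3 had 25 peaks from 55000001 on chromosome 3, where T47D had 2 and the colorectal lines none. T47D had 34 peaks from 101000001 on chromosome 11, against 12 in SKBR3, 2 in RKO and none in HCT116. RKO had 27 peaks from 13000001 on chromosome 8, against 5 in SKBR3, 1 in T47D and none in HCT116. HCT116 had 20 peaks from 30500001 on chromosome 4, against 4 in SKBR3, 4 in T47D and 3 in RKO, although its list was the shortest. An absence of peaks does not exclude a few missed calls, and no counting limit is given for bins picked in this way. Among unplaced contigs, GL000220.1 held 34 peaks in SKBR3, 43 in T47D, 27 in HCT116 and 44 in RKO.

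Equal list lengths and the other pairings were planned, but the values that would count for or against a cause were set for them after their results had been seen, and the test of crowding by called peaks was chosen after its result had been seen.

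The tissue pairing gave more regions of 1 pair alone than the other pairings, and most of them were breast regions. In the full lists the colorectal pair alone (2699) had fewer regions than SKBR3 with RKO (3845) or T47D with RKO (3212). With lists of equal length it had more (4186) than any pair of different tissue. Unequal list length as the whole cause of the pairing total is argued against, because with lists of equal length the tissue total was 3.43 times the larger of the other totals. The real pairing, with 23554 regions, was the 1 of 3 with a total as large, against 5041 for the highest other, and 3 pairings are too few for a share under 0.05. The excess of breast over colorectal regions was 7.73-fold in the full lists. It rose to 21.6-fold at a −log10 q of at least 10 and fell to 1.57-fold with lists of equal length. Depth cannot be told apart from a difference between the tissues in any of these values. A fixed threshold is reached more easily in a deeper library, and lists of equal length still differ in depth. Tissue of origin, as any other property shared by the lines of a tissue, stays open. Such properties include the duplicate share and the modelled fragment length, which split the lines as tissue does.

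Among the 5 bins in which the local background of SKBR3 had the largest unadjusted excess, crowding of the background window by called peaks could give that at chromosome 10, 49 to 50 Mb, which was -0.065 (centred log2) after adjustment, but gained copies or broadly open chromatin would raise called signal too and were not separated from it. In the 4 bins of raised background on chromosomes 8 and 17, excesses of 1.81 to 1.99 before adjustment left 0.55 to 0.70. The median left was 0.62, over an SD of 0.18, so the adjustment did not remove the excess there. These bins were picked for their unadjusted excess and grouped after the result was seen. Their values therefore cannot decide whether crowding is the whole cause. Sequence that draws reads equally in every line would cancel in a difference from the other lines; that 1 of 15 values of those lines lay in the top 5% of their own bins decides nothing further, as the bins had been picked for their excess over them. A candidate explanation is gained copies of chromosome segments in SKBR3, a line known for amplified ERBB2, a receptor tyrosine kinase gene on chromosome 17: neighbouring bins correlated with r = 0.254, and 0 of 1000 shuffles gave as much. The same correlation was 0.28 in T47D, 0.169 in HCT116 and 0.103 in RKO. The bins next to that on chromosome 17 lay above the other lines in T47D as well and below them in both colorectal lines. Regional chromatin therefore stays open beside copy number, and which genes the bins hold was not looked up.

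HCT116 had no peak across 5.76 Mb of chromosome 8. Fewer calls scattered singly among regions open in as many other lines are argued against, as 0 of 1000 permutations gave a run across as many such regions. Regions were not matched on peak strength, so weak regions missed together in this library of 1057628 tags are not excluded. The permutations break up any tendency of neighbouring regions to be open together, so closed chromatin across the stretch is not excluded. Lost sequence cannot be told apart from it: about 2093 tags are expected in the stretch at the library's mean, and tags outside peaks were not used here.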
